A study of Mus musculus with 7 samples.

How the data were processed

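Polyadenylated RNA from mouse cerebella at postnatal day 15 was sequenced with a directional library kit, as 3 WT and 4 L3mbtl3 KO/+ libraries, per the labels. Reads were handled with bcl2fastq, Trimmomatic 0.39, STAR 2.5.2a and RSEM 1.3.1, and the builds mm10 and GRCm38 were named, per the submitters' processing notes. The deposited expected counts, per the file headers, are RSEM's estimates of the reads of each gene or transcript and need not be whole. The deposited TPM and FPKM values, per the file headers, are scaled by transcript length and library size. The deposited isoform percentage, per the file headers, is the percent of a gene's transcripts that each transcript makes up. The strand setting and the settings of the aligner are not given in the sources used here.

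The per-library files held 55450 genes and 141767 transcripts, and all 55450 gene IDs were found in the GENCODE M21 annotation (GRCm38), from which gene names, positions and transcript types were taken. The 5 tables of the whole series that hold values were compared with the per-library files and not used. The gene and transcript tables named counts held TPM, and the transcript table named TPM held the isoform percentage. The gene tables had 17 extra lines, and their names went out of step with their values after 335 lines. All FPKM values of the gene table were equal to the per-library values line by line (tolerance 0.005), but 46.52% were equal by name. A further gene table named TPM held no values.

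Expected counts were rounded to whole numbers. Total counts were 37803045, 36269844 and 43761792 in WT and 35171610, 39660499, 33260001 and 29248360 in KO/+ libraries. No libraries agreed within sampling noise, so n was 3 and 4. Genes were filtered with filterByExpr and scaled by TMM factors (0.9783 to 1.022), and KO/+ was compared with WT with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) with no covariate, using Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The common biological coefficient of variation was 18.7%, and the median SE of a log2 fold change was 0.142 over all genes and 0.106 over the 10519 genes with a mean of at least 10 CPM. Fold changes are KO/+ relative to WT, with intervals at 95%. Transcripts were tested in the same way, without modelling the uncertainty of RSEM's assignment of reads to transcripts. L3mbtl3 and list means were also compared by exact permutation over the 35 splits of 7 libraries into 3 and 4.

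The design, gene lists, rule for named genes and alternatives, other than those given below as added, were fixed before the data were examined. The 25 lists covered Notch target genes, Notch pathway components and RBPJ cofactors, Hedgehog target genes, granule neuron progenitors, differentiating granule neurons, mature granule neurons, cell cycle, Purkinje cells, GABAergic interneurons, unipolar brush cells, Bergmann glia and astrocytes, oligodendrocyte precursors, myelinating oligodendrocytes, microglia, vascular cells, choroid plexus, meninges and fibroblasts, brainstem, red blood cells, immediate early genes, circadian clock, glucocorticoid-responsive genes, MBT-domain and Polycomb genes, mitochondrially encoded genes and sex genes. The sex genes were a check and were not tested as a set, and 23 lists had at least 4 members past the filter and were tested with camera (limma 3.58.1, preset correlation 0.01), with adjustment over lists. Boc and Sfrp1 are in both the Hedgehog and the progenitor list. A list's score is the mean log2 CPM of its members with a prior count of 2. Of the 9 lists that passed, 0 passed with an estimated correlation, and 0 passed with fry, where the smallest adjusted p was 0.874.

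The named genes were L3mbtl3; up to 12 genes per direction past the threshold with the largest fold change and no overlap between genotypes; where fewer than 5 passed, the genes of at least 1 mean CPM with the smallest unadjusted p up to 5 per direction; up to 4 members of each list with the smallest p; 12 fixed genes (Hes1, Hes5, Hey1, Heyl, Nrarp, Gli1, Ptch1, Atoh1, Mki67, Gabra6, Rbpj and Kdm1a); up to 4 called genes of the chromosome 10 window; and the L3mbtl3 transcripts with up to 4 other transcripts. Of the list members, the 2 with the smallest p were followed through the alternatives, except 1 member that is not reported here. The window around L3mbtl3 reached 20 Mb to each side.

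Alternatives were DESeq2 1.42.0, RLE, upper-quartile or no scaling factors, other filters on low counts, limma-voom, limma-trend on log2(TPM + 1) or log2(TPM + 0.1), the replicate number as a block, inferred sex as a covariate, a threshold of 0.1, other windows and leaving out each library. Library weights, list scores as covariates, inferred sex as a covariate for lists and 1 surrogate variable (sva 3.50.0) were added after the data were seen. R 4.3.3, Python 3.11.15 and SciPy 1.17.1 were used.

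The scripts were tested on simulated data with 200 changed genes of 16813, chosen among those with a mean of at least 1 CPM. On these, edgeR recovered 40.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 7 false calls, and DESeq2 recovered 53.7%, 83.6% and 100% with 53 false calls. When all members of the 23 lists were raised 1.3-fold, camera called 22, camera with an estimated correlation 20 and fry 21, and 1 of 200 unchanged random lists had an unadjusted p under 0.05 by camera. Each gene was drawn independently, so the simulated lists lack the correlation of the real ones, estimated at 0.973 for cell cycle. These rates therefore need not hold for the real lists.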

Results

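Messenger RNA was sequenced from the cerebella of mouse pups at postnatal day 15 (P15), an age at which granule neuron progenitors of the external granule layer are finishing their divisions and differentiating. The 7 libraries were made from 3 wild-type (WT) cerebella and from cerebella of 4 mice carrying 1 knockout and 1 wild-type allele of L3mbtl3 (L3mbtl3 KO/+). L3mbtl3 encodes a chromatin reader with MBT domains, which is known to bind the Notch transcription factor RBPJ and the histone demethylase KDM1A at Notch target genes. The comparison asks which transcripts differ in the cerebellum when L3mbtl3 has 1 functional allele. Between 29248360 (KO/+ replicate 4) and 43761792 (WT replicate 3) expected counts were assigned to genes per library. The design text counts 4 KO/+ mice but gives only the number of WT cerebella, and litters are not given, so p-values of genes, transcripts and list means measure the spread between these samples. Those of camera with the preset correlation of 0.01 compare the genes of a list with other genes. They take the genes as nearly independent and do not measure the spread between samples.

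L3mbtl3 lies on chromosome 10 from 26274468 to 26375971 on the minus strand (GRCm38; ENSMUSG00000039089.15). Its normalised read count, scaled to library size as CPM, was 24.17 ± 2.25 (SD, n = 3) in WT and 20.6 ± 2.55 (SD, n = 4) in KO/+ cerebella, so that KO/+ libraries held 85.2% of the WT level. The WT libraries stood at 22.6, 26.8 and 23.2 CPM and the KO/+ libraries at 19.7, 17.4, 22.3 and 23.0 CPM, with KO/+ replicate 4 above WT replicate 1. The exact permutation test over the 35 splits of the 7 libraries gave p = 0.0571 one-sided and p = 0.143 two-sided, where the smallest possible one-sided p is 0.0286. In the edgeR quasi-likelihood fit the log2 fold change was -0.23 (SE 0.12; 95% interval -0.50 to 0.04; Benjamini-Hochberg adjusted p = 0.957), an interval that excludes a log2 change of -1. The labels do not give the deleted part of the gene, and KO/+ and WT libraries overlapped, so the level of L3mbtl3 does not check the genotype labels here.

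**Figure D1:**
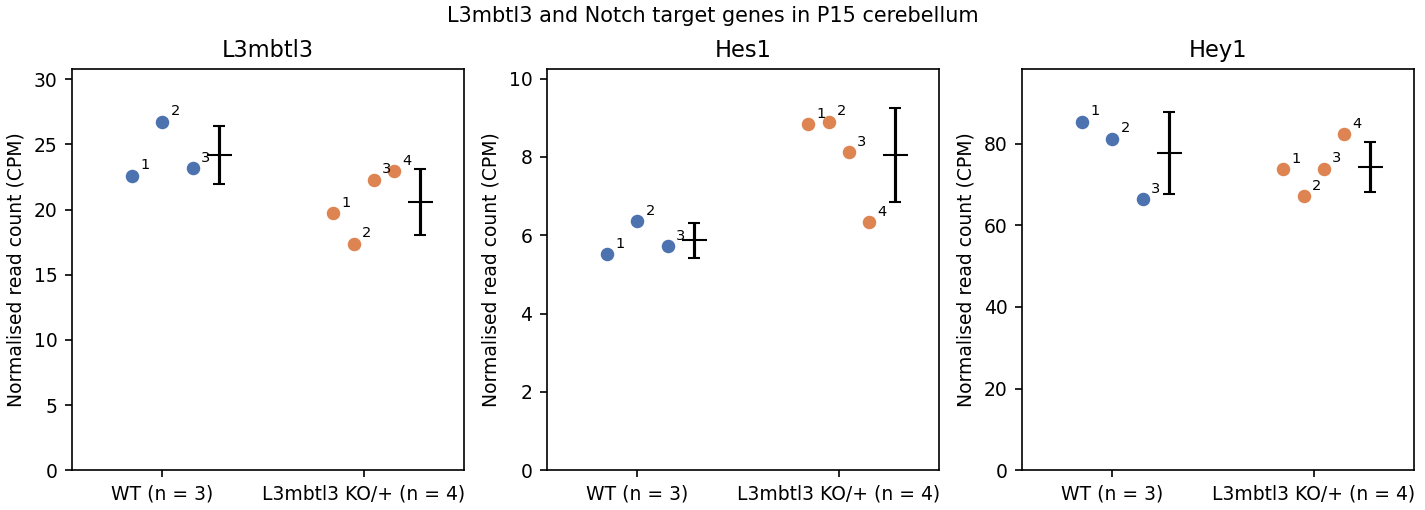
Normalised read counts (CPM) of L3mbtl3, Hes1 and Hey1 in each library. Points are libraries with their replicate numbers, and the bar beside each group is its mean ± SD (n = 3 WT, n = 4 KO/+). L3mbtl3 had a mean of 24.17 CPM in WT and 20.6 CPM in KO/+ with overlapping groups, and Hes1 was at 6.33 CPM in KO/+ replicate 4, inside the WT range.

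No gene separated the genotypes after correction for multiple testing. Of the genes with higher values in KO/+, the 5 with the smallest unadjusted p were Eif3j2, Tpt1-ps3, Dcn, Gm28529 and Rsad2. Eif3j2, a copy of a translation initiation factor subunit gene, had a log2 fold change of 3.43 (SE 0.70), at 1.86 ± 0.237 CPM in WT (SD, n = 3) and 19.997 ± 11.5 CPM in KO/+ (SD, n = 4), with KO/+ replicate 4 at 2.81 CPM. Its level is uncertain, since 90.8% of the 50-base windows of its transcript also occur in transcripts of Eif3j1, and the CPM of both genes summed to 73.6 ± 6.62 in WT (SD, n = 3) and 74.8 ± 0.884 in KO/+ (SD, n = 4). Dcn, which encodes the fibroblast proteoglycan decorin, was at 35.1 ± 1.35 CPM in WT and 46.4 ± 5.69 CPM in KO/+ (log2 fold change 0.40, SE 0.10), and the interferon-inducible gene Rsad2 was at 0.644 ± 0.138 CPM and 1.44 ± 0.462 CPM (log2 fold change 1.17, SE 0.31). The log2 fold changes of Tpt1-ps3, a processed pseudogene that can share reads with its parent gene, and the antisense gene Gm28529 were 0.56 (SE 0.14) and 0.96 (SE 0.26). Among genes with lower values in KO/+, Tmem267 (log2 fold change -0.95, SE 0.21), the zinc finger gene Ikzf5 (-0.83, SE 0.19), Nbas (-0.38, SE 0.10), the pro-apoptotic BH3-only gene Bmf (-0.56, SE 0.15) and the peroxidase gene Lpo (-0.57, SE 0.16) had the smallest unadjusted p. None of these 10 genes passed the threshold, each having an adjusted p of 0.957 by edgeR.

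Over 16813 genes tested, edgeR's quasi-likelihood test called 0 genes at a Benjamini-Hochberg adjusted p under 0.05, with 530 genes at an unadjusted p under 0.05 (210 higher and 320 lower in KO/+) where chance gives 841. DESeq2 called 0 genes with 597 at an unadjusted p under 0.05, limma-voom 0 with 497, and limma-trend on log2(TPM + 1) 0 with 443. The edgeR count at an unadjusted p under 0.05 was 180 without KO/+ replicate 1 and without KO/+ replicate 2, 975 without WT replicate 3 (5.75% of genes) and 1562 without KO/+ replicate 4 (9.32%). The CPM of the genotypes did not overlap for 363 genes higher and 302 genes lower in KO/+, which is 3.96% of the genes tested where chance gives 5.71%. The count became 1 without WT replicate 2 (Wdfy1, edgeR adjusted p = 0.0231), without WT replicate 3 (Fam220a, 3.2e-05) and without KO/+ replicate 4 (Eif3j2, 3.71e-04); Wdfy1 and Fam220a were chosen after their values were seen, and Fam220a has a pair of overlapping gene models that can share reads. Of the 66 named genes followed through the alternatives, 41 had a log2 fold change that moved by over 1.5 times or changed sign when 1 library was left out. For 26 of them a lowest or highest value that moved so came without WT replicate 3. On counts simulated for the 16813 genes of this comparison, the same test recovered 40.3% of changes of 1.5-fold, 76.1% of 2-fold changes and 98.5% of 4-fold changes. The changed genes had a mean of at least 1 CPM and each gene was drawn independently. Variation that many genes of a library share was therefore not simulated, and recovery in the real libraries may differ.

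Notch target genes did not move together in KO/+ cerebella. Of the 15 members measured, 7 had positive and 8 negative log2 fold changes (median -0.02), 0 passed adjusted over all genes and 0 passed adjusted over the list alone. Hes1, the transcriptional repressor that is a canonical Notch target, had the smallest p of the list, with 5.87 ± 0.442 CPM in WT (SD, n = 3) and 8.05 ± 1.20 CPM in KO/+ (SD, n = 4; log2 fold change 0.46, SE 0.15, edgeR adjusted p = 0.957). The log2 fold changes of Hes5, Hey1, Heyl and Nrarp were 0.18 (SE 0.21), -0.06 (SE 0.11), -0.32 (SE 0.31) and -0.12 (SE 0.12), and that of Dtx4 was -0.19 (SE 0.12). Leaving out 1 library moved Hes5 to between 0.065 (without KO/+ replicate 3) and 0.33 (without WT replicate 3), Heyl to between -0.51 (without KO/+ replicate 3) and -0.09 (without WT replicate 3) and Nrarp to between -0.19 (without WT replicate 2) and -0.006 (without WT replicate 3). Hey1 reached 0.003 without WT replicate 1. The set test camera gave an adjusted p of 0.872 for the list, and its adjusted p with an estimated correlation was 0.909.

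Components of the Notch pathway and RBPJ cofactors passed camera as a group lower in KO/+ (adjusted p = 0.0138), with 24 of 31 members negative and a median log2 fold change of -0.08. The adjusted p = 0.851 with an estimated correlation, and the exact permutation test of the list means gave p = 0.143. None of the members passed adjusted over all genes or adjusted over the list alone. The extreme member was Dlk1, a non-canonical Notch ligand, with a log2 fold change of -2.97 (SE 0.91), and its CPM was 8.18 in WT replicate 3 and at most 1.35 elsewhere, so that without this library the log2 fold change was -1.01. The ligand gene Dll3 was at a log2 fold change of -0.57 (SE 0.21), while Rbpj and Kdm1a, which encode the known partners of L3MBTL3, were at -0.05 (SE 0.15) and -0.05 (SE 0.14). The list's call was lost without WT replicate 2 (adjusted p = 0.201), KO/+ replicate 1 (0.135) or KO/+ replicate 2 (0.0938), and with the cell cycle (0.141) or choroid plexus score (0.0565) as a covariate, both added after the data were seen.

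Genes of dividing granule neuron progenitors varied more between libraries of 1 genotype than between genotypes. The cell cycle list had 29 of 30 members with negative log2 fold changes (median -0.27), but its mean log2 CPM was 5.05, 5.10 and 3.67 in the WT libraries and 3.97, 3.75, 4.79 and 4.95 in the KO/+ libraries. The proliferation marker Mki67 was at 194, 209 and 63.6 CPM in WT and at 63.5, 61.4, 152 and 180 CPM in KO/+ (log2 fold change -0.45, SE 0.50), and Bub1b and Mcm4 were at -0.54 (SE 0.38) and -0.31 (SE 0.24). The progenitor transcription factor Atoh1 (-0.50, SE 0.53), Mfap4 (-0.77, SE 0.54), the Hedgehog effector Gli1 (-0.28, SE 0.27) and Gli3 (-0.38, SE 0.20) were negative, while the Hedgehog receptor Ptch1 was at -0.04 (SE 0.08), Zic1 at 0.17 (SE 0.13) and Gas1 at 0.09 (SE 0.07). Without WT replicate 3 Mki67, Bub1b and Mcm4 were at -0.82, -0.87 and -0.54, and without WT replicate 2 at -0.18, -0.34 and -0.13. Leaving out 1 library moved Atoh1 to between -0.89 (without WT replicate 3) and -0.20 (without WT replicate 1), Mfap4 to between -1.26 (without KO/+ replicate 4) and -0.37 (without WT replicate 1) and Gli1 to between -0.51 (without WT replicate 3) and -0.15 (without WT replicate 2). Zic1 was at 0.03 without WT replicate 3 and 0.25 without WT replicate 1, Gli3 at -0.52 without KO/+ replicate 4 and -0.24 without KO/+ replicate 1, Gas1 at 0.06 without WT replicate 2 and 0.14 without WT replicate 3, and Ptch1 at -0.08 without KO/+ replicate 3 and 0.01 without KO/+ replicate 1.

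Cell cycle genes passed camera lower in KO/+ (adjusted p = 5.26e-03), with adjusted p = 0.851 with an estimated correlation, and the exact permutation test of the list means gave p = 0.657. The Hedgehog target list (12 of 14 members negative, median -0.21) and the granule neuron progenitor list (8 of 12 negative, median -0.11) did not pass, with camera adjusted p of 0.117 and 0.554. The Hedgehog list also holds pathway components such as Smo, Boc and Gas1, so its members need not share a direction. No member of the 3 lists passed adjusted over all genes or adjusted over the list alone. The cell cycle call was lost without WT replicate 1 (adjusted p = 0.978), WT replicate 2 (0.924, in the other direction), KO/+ replicate 1 (0.176) or KO/+ replicate 2 (0.805). The Hedgehog list passed without WT replicate 3 (4.19e-04) or KO/+ replicate 3 (0.0165), and the progenitor list passed without WT replicate 3 (1.01e-03). With inferred sex as a covariate, added after the data were seen, both passed (0.00234 and 0.047).

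**Figure D2:**
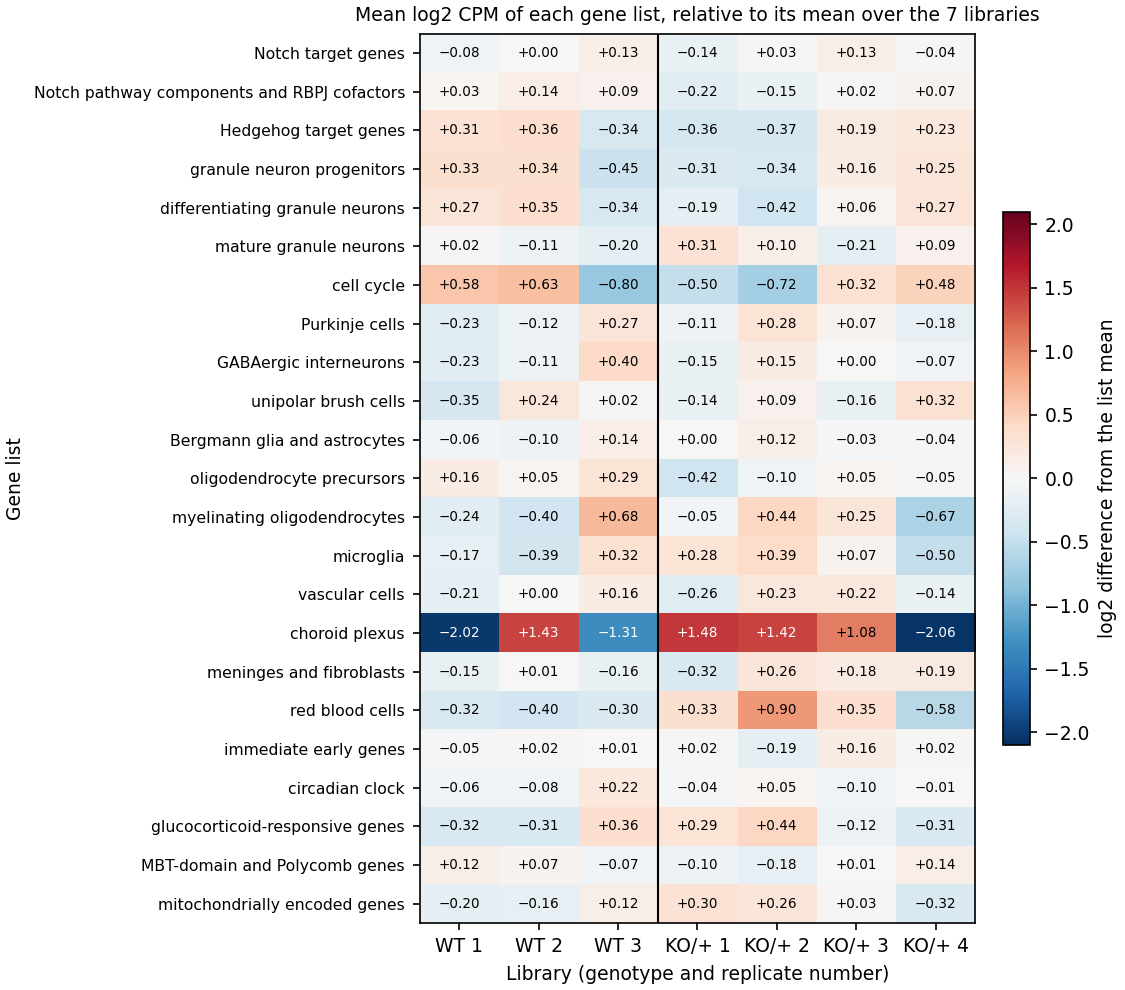
Mean log2 CPM of each of the 23 gene lists tested in each library, as the difference from that list's mean over the 7 libraries, with red higher and blue lower. The vertical line parts WT from KO/+. The cell cycle list spans 1.43 on the log2 scale and the choroid plexus list 3.54, with low and high libraries in both genotypes.

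The lists of differentiating and mature granule neurons had opposite signs. Differentiating granule neuron genes were lower in KO/+ by camera (adjusted p = 0.0142), with 11 of 12 members negative and a median log2 fold change of -0.19, and adjusted p = 0.851 with an estimated correlation. The exact permutation test of the list means gave p = 0.514, and the mean log2 CPM was 8.05, 8.13 and 7.44 in WT and 7.59, 7.36, 7.84 and 8.05 in KO/+ libraries, low in the libraries with low cell cycle scores. Astn1, an adhesion protein of migrating granule neurons, was at -0.33 (SE 0.13) and the semaphorin gene Sema6a at -0.32 (SE 0.18). Mature granule neuron genes were higher (adjusted p = 4.79e-04), with 12 of 14 members positive and a median of 0.25, and adjusted p = 0.851 with an estimated correlation. The exact permutation test of its list means gave p = 0.314, with mean log2 CPM of 8.50, 8.37 and 8.28 in WT and 8.79, 8.58, 8.27 and 8.57 in KO/+ libraries. The synaptic organiser Cbln1 was at 0.31 (SE 0.14), the vesicular glutamate transporter Slc17a7 at 0.31 (SE 0.15) and the GABA-A receptor subunit Gabra6 at 0.35 (SE 0.20). No member of either list passed adjusted over all genes or adjusted over the list alone. The call of the differentiating list was lost without WT replicate 1 (adjusted p = 0.492), WT replicate 2 (0.713) or KO/+ replicate 2 (0.479), and with the cell cycle (0.485) or choroid plexus score (0.0565) as a covariate, both added after the data were seen; that of the mature list was lost without WT replicate 3 (0.087).

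Oligodendrocyte precursor genes were lower in KO/+ by camera (adjusted p = 1.64e-05), with 10 of 10 members negative and a median log2 fold change of -0.28. The adjusted p = 0.714 with an estimated correlation, and the exact permutation test of the list means gave p = 0.0571. Gpr17, a receptor of differentiating precursors, was lower in every KO/+ library than in every WT library, with a log2 fold change of -0.59 (SE 0.20), and the proteoglycan gene Cspg4 (NG2) was at -0.51 (SE 0.23). Neither passed adjusted over all genes or adjusted over the list alone. Myelinating oligodendrocyte genes split 8 positive to 7 negative (camera adjusted p = 0.556), with Myrf at -0.49 (SE 0.23) and Mag at -0.32 (SE 0.22); the list's median was 0.01 and its mean -0.04. Without WT replicate 3 Myrf was at -0.24 and Mag at -0.03. This list passed without WT replicate 2 (adjusted p = 0.011), WT replicate 3 (0.00403, in the other direction) or KO/+ replicate 2 (0.0205).

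Lists of choroid plexus, red blood cell and meningeal genes passed camera as higher in KO/+, but in each of them a KO/+ library had the lowest score of all 7 libraries, and exact permutation tests of the list means gave p = 0.429, 0.143 and 0.229. All 12 choroid plexus members were positive (median 0.56, camera adjusted p = 9.17e-04), including Kcnj13 at 1.05 (SE 0.76) and Calml4 at 1.07 (SE 0.81), and adjusted p = 0.851 with an estimated correlation. Without WT replicate 1 Kcnj13 and Calml4 were at 0.67 and 0.58, and without WT replicate 2 at 2.21 and 1.91. The list's mean log2 CPM was 0.86, 4.31 and 1.57 in WT and 4.36, 4.30, 3.96 and 0.82 in KO/+. All 7 red blood cell members were positive (median 0.82, adjusted p = 4.43e-07), including Hbb-bs, a haemoglobin gene with a near-identical copy, at 0.88 (SE 0.32) and the haem synthesis gene Alas2 at 0.90 (SE 0.33), and adjusted p = 0.714 with an estimated correlation. The red blood cell score was 4.15, 4.07 and 4.17 in WT and 4.80, 5.37, 4.82 and 3.89 in KO/+. Meningeal and fibroblast genes were positive for 9 of 12 members (median 0.26, adjusted p = 1.87e-04), with Aldh1a2 at 0.46 (SE 0.15), and adjusted p = 0.714 with an estimated correlation. Dcn was the 1 member of these lists that passed adjusted over the list alone, and 0 passed adjusted over all genes. The choroid plexus call was lost without WT replicate 1 (adjusted p = 0.193) or WT replicate 3 (0.2), and with the cell cycle score as a covariate (0.0771). The meningeal call was lost with inferred sex as a covariate (adjusted p = 0.35), and both covariates were added after the data were seen.

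Mitochondrially encoded transcripts were higher in KO/+ by camera (adjusted p = 4.59e-03), with 12 of 13 members positive and a median log2 fold change of 0.16, and adjusted p = 0.851 with an estimated correlation. The exact permutation test of the list means gave p = 0.4. mt-Atp6 was at 0.31 (SE 0.16) and mt-Co3 at 0.23 (SE 0.17), and no member passed adjusted over all genes or adjusted over the list alone. All genes of the mitochondrial genome, including those outside the list, took 3.32%, 3.41% and 3.96% of the counts in WT libraries. In KO/+ libraries they took 4.74%, 4.55%, 3.75% and 3.16%. The call was lost without WT replicate 1 (adjusted p = 0.173), WT replicate 2 (0.0665), KO/+ replicate 1 (0.163) or KO/+ replicate 2 (0.0889), and with the cell cycle (0.141) or choroid plexus score (0.288) as a covariate, both added after the data were seen.

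The other 10 lists did not pass camera. Their adjusted p was 0.273 for Purkinje cells (Foxp2 -0.73, SE 0.33; Calb1 0.25, SE 0.17), 0.0769 for microglia (Tyrobp 0.33, SE 0.21; C1qb 0.29, SE 0.21), 0.257 for glucocorticoid-responsive genes (Pdk4 0.41, SE 0.24), 0.368 for immediate early genes (Arc -0.50, SE 0.25; Jun 0.12, SE 0.06), 0.463 for circadian clock genes (Ciart -0.29, SE 0.13; Cry1 0.15, SE 0.07) and 0.554 for vascular cells (Rgs5 0.23, SE 0.17). It was 0.556 for GABAergic interneurons (Pvalb 0.32, SE 0.20; Nxph1 -0.30, SE 0.24), for unipolar brush cells (Lmx1a 0.41, SE 0.34), for Bergmann glia and astrocytes (Ptprz1 -0.30, SE 0.12; Hopx 0.17, SE 0.08) and for MBT-domain and Polycomb genes (Scml4 -0.82, SE 0.42; Eed 0.16, SE 0.09). None of the members of these 10 lists passed adjusted over all genes or adjusted over the list alone. Without WT replicate 3, the lists of Purkinje cells (adjusted p = 0.00235), microglia (4.51e-04), glucocorticoid-responsive genes (0.00613), GABAergic interneurons (0.0209, in the other direction) and MBT-domain and Polycomb genes (0.0276) passed. Without that library Foxp2 was at -0.17, Scml4 at -0.28, Arc at -0.13, Ptprz1 at -0.17, Ciart at -0.18, Eed at 0.08 and Nxph1 at 0.07. Calb1 (0.38), Pvalb (0.43), Tyrobp (0.50) and Pdk4 (0.60) were then further from no change. Lmx1a ran from 0.19 without WT replicate 1 to 0.91 without WT replicate 2. Microglia passed with inferred sex as a covariate (6.9e-04), added after the data were seen. Purkinje cells also passed without KO/+ replicate 1 (0.0333) or KO/+ replicate 4 (0.0312), microglia without KO/+ replicate 4 (1.52e-04), vascular cells without KO/+ replicate 1 (0.0169) and GABAergic interneurons without WT replicate 1 (0.0433). The brainstem list was not tested as a set in the main comparison, because 3 of its 16 genes passed the filter on low counts. With no filter, and without WT replicate 1 or WT replicate 2, 24 lists were tested, the brainstem list among them. WT replicate 3 held 231 expected counts of the serotonin transporter gene Slc6a4 and 264 of Tph2. Any other library held at most 2 and at most 44, and both genes were chosen after their values were seen.

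Genes near the targeted locus were examined because a knockout allele carries linked sequence of the strain it was made in. Within 20 Mb of L3mbtl3, from 6274468 to 46375971 on chromosome 10, edgeR called 0 of 185 tested genes, as it called 0 of 16627 elsewhere, and 5 of the 185 (2.70%) were at an unadjusted p under 0.05, against 3.15% of all genes. Without KO/+ replicate 4 these shares were 7.10% and 9.32%. Fisher's exact test, two-sided, gave p = 1, which carries no information with no called gene, and camera on the same genes gave p = 0.722. Camera looks for a shared direction, so linked genes moved both ways would escape it. The median log2 fold change of the window was -0.01. Ahi1, a ciliary gene chosen after its values were seen, had the smallest unadjusted p of the window, 0.0369 by edgeR.

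At the transcript level, edgeR called 0 of 44375 transcripts, with 1201 at an unadjusted p under 0.05 (2.71%), whereas DESeq2 called 46 transcripts (27 higher and 19 lower in KO/+), of which 25 had 0 counts, after rounding to whole numbers, in every library of 1 genotype. The 4 transcripts with the smallest p in edgeR were Adgrl3-217, Slc35c2-203, Senp2-205 and Ttc3-227. Adgrl3-217 had 67.7, 91.5 and 119.3 expected counts in the WT libraries and 0 in each KO/+ library, and Slc35c2-203 had 0 in each WT library and 81.8, 65.8, 34.5 and 49.5 in the KO/+ libraries (edgeR adjusted p = 0.486 each). Senp2-205 and Ttc3-227 were likewise at 0 in every KO/+ library (adjusted p = 0.486 and 0.530). The 4 genes as a whole had log2 fold changes of -0.25 (Adgrl3, SE 0.10), 0.05 (Slc35c2, SE 0.10), -0.001 (Senp2, SE 0.10) and -0.02 (Ttc3, SE 0.10), and RSEM divides the reads of a gene among its annotated transcripts, so these values depend on that assignment. The count became 2 without WT replicate 3 (Fam220a-204 and Fam220a-208, edgeR adjusted p = 4.55e-04 each) and 1 without KO/+ replicate 4 (Eif3j2-201, 0.00165), all named after their values were seen. On counts simulated for the 44375 transcripts of this comparison, edgeR recovered 1.49% of changes of 1.5-fold, 23.9% of 2-fold and 69.7% of 4-fold changes with 9 false calls, and DESeq2 recovered 17.9%, 58.2% and 95.5% with 99 false calls. The changed transcripts had a mean of at least 1 CPM, and each transcript was drawn independently, without variation shared within a library.

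The L3mbtl3 transcripts did not separate the genotypes either. The protein-coding L3mbtl3-202 was at 4.23 ± 0.580 TPM in WT (SD, n = 3) and 3.36 ± 0.796 TPM in KO/+ (SD, n = 4; exact two-sided permutation p = 0.171), and made up 39.8% ± 8.86 and 36.8% ± 5.71 of the gene's transcripts by RSEM's isoform percentage. L3mbtl3-205, a processed transcript, was at 4.34 ± 1.52 TPM in WT and 3.69 ± 0.602 TPM in KO/+ (exact two-sided permutation p = 0.543). L3mbtl3-201 was at 0.873 ± 0.546 and 0.468 ± 0.385 TPM, L3mbtl3-203 at 1.18 ± 0.552 and 1.46 ± 1.02 TPM, and L3mbtl3-204 at 0.203 ± 0.0603 and 0.135 ± 0.0819 TPM. L3mbtl3-206 was listed at 0 in each library, and L3mbtl3-207 reached at most 0.01 TPM.

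**Figure D3:**
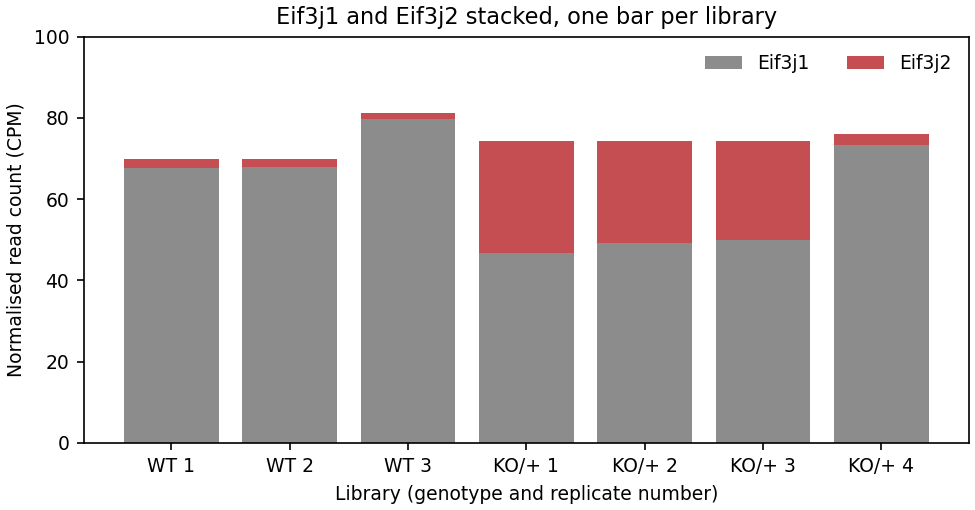
Normalised read counts (CPM) of Eif3j1 (grey) and Eif3j2 (red), stacked in 1 bar per library. Eif3j2 was at 24.4 CPM or more in KO/+ replicates 1 to 3 and at 2.81 CPM or less in the other libraries, while the sum of both genes lay between 69.8 and 81.3 CPM.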

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

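Of 96 values of KO/+ libraries, 6 had 1 library far from the other 3, judged by the gap to the nearest library as a share of the range against Dixon's 95% critical value, where chance gives 4.8. All explanation tests here were chosen after the result was seen, except that of the transcript sequence shared by Eif3j1 and Eif3j2.

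The choroid plexus score was 0.82 in KO/+ replicate 4 and at least 3.96 in the other KO/+ libraries (gap share 0.887). Genotype as the whole cause is excluded, because the range within a genotype was 100% of the range over all libraries, with scores of 0.86, 4.31 and 1.57 in WT. The members moved together within genotype, with a mean residual correlation of 0.796, and 11 of 12 differed over 2-fold between libraries. A candidate explanation is choroid plexus tissue taken along in some dissections, which these values fit. They do not tell it from other causes of joint variation, since lists such as cell cycle (0.973) and microglia (0.912) had correlations as high. Whether genotype adds to the spread stays open.

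Eif3j2 was at 2.81 CPM in KO/+ replicate 4 and at least 24.4 CPM in the other KO/+ libraries (gap share 0.872). Its reads may be shared with Eif3j1: the summed CPM of both genes had a highest to lowest ratio of 1.16 while Eif3j2 alone had 17.3, and 90.8% of the 2330 windows of 50 bases in the Eif3j2 transcript occur in an Eif3j1 transcript. Strain variants linked to Eif3j1 on chromosome 2 stay open. Of 222 genes within 10 Mb, 6.31% had an unadjusted p under 0.05 against 3.10% elsewhere (Fisher's exact test, two-sided, p = 0.0173). The same test was run over 139 fixed windows of 20 Mb, which were not centred on Eif3j1, so that stretch itself was not scanned. The fixed window holding Eif3j1 had an adjusted p of 0.868, and 1 other window passed (chromosome 16, 60 to 80 Mb, 6 of 29 genes, adjusted p = 0.0333). An effect of genotype cannot be told apart either, with an exact two-sided permutation p of 0.0571.

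The meningeal and fibroblast score was 4.23 in KO/+ replicate 1 and at least 4.73 in the other KO/+ libraries (gap share 0.862). Ciart was at 6.74 CPM in KO/+ replicate 2 and at most 6.10 CPM in the others (0.862). Eed was at 31.2 CPM in KO/+ replicate 1 and at most 28.1 CPM in the others (0.964). L3mbtl3-205 was at 4.59 TPM in KO/+ replicate 4 and at most 3.46 TPM in the others (0.904).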

How the results depend on the processing

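The 0 genes past the threshold stayed 0 with DESeq2, RLE, upper-quartile or no factors, both other filters, limma-voom, limma-trend and inferred sex. In edgeR the count also stayed 0 with a threshold of 0.1. It stayed 0 too with the cell cycle or choroid plexus score as a covariate, both added after the data were seen. DESeq2 was not counted at 0.1, but its smallest adjusted p was 0.0679, which would pass there. The count was 1 with the replicate block (Eif3j2, log2 fold change 3.79, edgeR adjusted p = 0.0437), 1 with 1 surrogate variable (Gm6969, edgeR) and 1 with limma-voom library weights (Fam220a), the last 2 added after the data were seen, and 0 to 1 leaving out single libraries. No WT library shares the number of KO/+ replicate 4, so with the block it adds nothing to the genotype estimate. Eif3j2 was likewise at 3.78 with that library left out. Genes at an unadjusted p under 0.05 numbered from 146 (choroid plexus score) to 4346 (library weights, 25.8% of genes); they were above the 5% that chance gives also with 1 surrogate variable (2915), the cell cycle score (1068), the replicate block (1029) and without WT replicate 3 or KO/+ replicate 4. L3mbtl3 stood at 84% (TPM), 86.6% (FPKM) and 84.9% (RLE) of WT, and at 81.9% to 90% leaving out single libraries. The median SE of a log2 fold change was 0.142 over all genes and 0.106 over those with a mean of at least 10 CPM. The cause was not tested for any change below, except where a score was fitted against its own list.

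Same-numbered WT and KO/+ libraries had correlations of 0.086, -0.17 and -0.022, and not every library correlated best with its own number, so the numbers were not taken to pair samples. With the replicate block, which leaves KO/+ replicate 4 out of the genotype estimate, 10 lists passed camera in place of 9. Myelinating oligodendrocytes changed direction (camera adjusted p = 0.117), microglia passed (3.5e-04), and transcripts stayed at 0.

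Of 66 named genes, 5 changed direction when a library was left out: Hey1 (-0.167 to 0.003), Ptch1 (-0.081 to 0.014), Rbpj (-0.179 to 0.02), Kdm1a (-0.175 to 0.03) and Nxph1 (-0.473 to 0.07). Eif3j2 ran from 3.23 to 3.78.

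With an estimated correlation 0 lists passed (adjusted p = 0.714 for oligodendrocyte precursors, meninges and red blood cells and 0.851 for the other 6), and with fry 0 (0.874). RLE factors, no factors and no filter changed no list. With the cell cycle score as a covariate 4 passed: lost were Notch components (0.141), differentiating granule neurons (0.485), choroid plexus (0.0771) and mitochondrial genes (0.141), and progenitors (0.749) and MBT-domain and Polycomb genes (0.623) changed direction; the cell cycle list (0.944) was fitted with its own score, so its loss tests nothing. With the choroid plexus score 5 passed: lost were Notch components (0.0565), differentiating granule neurons (0.0565) and mitochondrial genes (0.288); the loss of choroid plexus (0.988) is likewise fixed by its own score. With inferred sex 11 passed: gained were Hedgehog targets (0.00234), progenitors (0.047) and microglia (6.9e-04), meninges (0.35) was lost, and unipolar brush cells (0.939), myelinating oligodendrocytes (0.692) and vascular cells (0.304) changed direction.

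Leaving out single libraries gave 6 to 15 lists, the latter without WT replicate 3. Without WT replicate 1 or WT replicate 2, 24 lists were tested and 7 passed in each case, the brainstem list among them. The adjusted p of that list is not given here. Oligodendrocyte precursors, meninges and red blood cells passed throughout. The camera adjusted p ran from 0.509 to 0.979 for Notch targets, 0.00291 to 0.201 for Notch components, 4.19e-04 to 0.914 for Hedgehog targets, 0.00101 to 0.993 for progenitors, 2.21e-06 to 0.713 for differentiating and 6.07e-09 to 0.087 for mature granule neurons, and 2.64e-16 to 0.978 for cell cycle. It ran from 0.00235 to 0.884 for Purkinje cells, 0.0209 to 0.993 for GABAergic interneurons, 0.201 to 0.981 for unipolar brush cells, 0.087 to 0.978 for Bergmann glia, 0.00403 to 0.711 for myelinating oligodendrocytes, 1.52e-04 to 0.924 for microglia and 0.0169 to 0.902 for vascular cells. It ran from 4.08e-18 to 0.2 for choroid plexus, 0.0637 to 0.78 for immediate early genes, 0.0665 to 0.797 for circadian genes, 0.00613 to 0.954 for glucocorticoid-responsive genes, 0.0276 to 0.924 for MBT-domain and Polycomb genes and 6.67e-07 to 0.173 for mitochondrial genes.

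Near L3mbtl3, 0 genes were called with every window and library left out, and camera p ran from 0.24 to 0.909. DESeq2 called 46 transcripts; edgeR called 0 with a mean CPM of at least 1 and 0 to 2 leaving out single libraries.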

Other observations

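Some members of the brainstem list were highest in WT replicate 3, while Hoxa2, Hoxb3, Hoxb5 and Hoxc4, at 10 or fewer counts, were highest in KO/+ replicate 4. These members were chosen after their values were seen. Fev, a transcription factor of serotonin neurons, had 13 expected counts in WT replicate 3 and 0 in the other 6 libraries, and Slc5a7, the choline transporter gene, had 173 against 37 to 61. Meis2, chosen after its values were seen, was at 29.7 CPM in WT replicate 3 and at most 3.45 CPM elsewhere.

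The processed pseudogene Gm15459, chosen after its values were seen, was at 498 and 469 CPM in WT replicates 1 and 2 and 476 CPM in KO/+ replicate 4, and at 8.51 to 11.6 CPM in the other 4 libraries. Xist and Y-linked genes put WT replicates 1 and 3 and KO/+ replicate 1 as female and the other 4 libraries as male.

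The spread of the cell cycle score was weighed with tests chosen after the result was seen. The score ranged over 1.43 on the log2 scale. Genotype and pup sex are each excluded as the whole cause, because the range within a genotype reached 100% and that within a sex 96.5% of the whole. Dilution by outside tissue that lacks mature granule neuron transcripts is excluded as the whole cause, since the mature granule neuron score spanned 36.4% of that range and 0 of its 14 members reached it. A part played by such tissue is not excluded. WT replicate 3, with the lowest cell cycle score (3.67), held 231 expected counts of Slc6a4, a gene chosen after its values were seen. KO/+ replicates 1 and 2, also low at 3.97 and 3.75, held 0 and 1. Differences in the stage of the external granule layer between pups stay open, as untested.

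Splits of the 7 libraries into 3 and 4, a test chosen before the result was seen, do not exclude chance for the lists: 21 of 35, the real split among them, gave at least the real 9, with a highest other of 16. For genes and transcripts the real count was 0, so that 35 of 35 splits had to reach it and nothing was tested; the highest others were 2254 and 884. Splits that call many genes point to a structure of the samples other than genotype. The split with 2254 genes set WT replicate 3 and KO/+ replicates 1 and 2 apart. These libraries had the lowest cell cycle scores (3.67, 3.97 and 3.75).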
